A study of Mus musculus with 24 samples.

How the data were processed

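RNA was sequenced from 24 samples of mouse CD4 T cells made into Th17 cells in culture, in 8 groups of 3 biological repeat experiments. Per the labels' protocols, naive CD4 T cells from C57BL6 spleens were activated for 3 days with plate-bound anti-CD3 (2 µg/ml) and anti-CD28 (10 µg/ml). The medium held TGFβ1 (2 ng/ml), IL-6 (50 ng/ml) and antibodies to interferon gamma, IL-4 and IL-12p40. One set of cultures received IL-2 (10 ng/ml) and the other an antibody against IL-2 (10 µg/ml). Cells were restimulated for 4 h with phorbol dibutyrate and ionomycin (500 ng/ml each), fixed, permeabilised, stained inside the cell for IL-17A and IL-10, and sorted. Per the same protocols, RNA was extracted from fixed cells with a kit made for paraffin-embedded tissue, and libraries were made with a TruSeq RNA v2 kit, which does not mark the strand. The treatment field of the 9 antibody-treated samples reads anti-IL-12, whereas their titles, source names, descriptions and the culture protocol say anti-IL-2. They were taken as anti-IL-2, because the protocol adds an antibody against IL-12p40 to all cultures.

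Per the file headers, the deposited table holds raw reads aligned against transcriptome and genome for 53342 genes in 24 columns, all of which were matched to a sample. The deposited values are expected counts: between 82.2% and 83.6% of the non-zero values in a library were fractional. The authors' aligner and counting tool are not given in the sources used here. The submitters' processing notes name the GRCm38 (mm10) build, DESeq2 1.10.1 and R 3.2.3, and do not say what DESeq2 was used for. Expected counts were rounded to whole numbers. The largest change this made to a library's total was 0.00158% of the largest total. Totals ran from 24.7 to 43.6 M counts per library, and 23723 to 26229 genes had at least 1 count. Gene positions are those of GENCODE vM21 on GRCm38, in which 53237 of the 53342 identifiers (99.8%) were found. The annotation release behind the deposited table is not given in the sources used here, so it may differ.

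All 24 libraries were fitted together in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with 1 coefficient per group. Genes were kept by filterByExpr with a minimum count of 10, which left 18479 genes. Libraries were scaled by trimmed mean of M-values, and each comparison used edgeR's quasi-likelihood test with 16 residual degrees of freedom. The coefficient of biological variation was 11.8%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and log2 changes are given with an approximate standard error (SE). This SE is the size of the log2 change divided by the square root of the F value of its test. Expression is given as CPM, counts scaled to a common library total by the same factors, as means with the standard deviation (SD) of 3 libraries. The 10 comparisons were IL-2 against anti-IL-2 in unsorted, double negative and IL-17 single positive cells, 5 comparisons between sorted populations within a culture, and 2 interactions. The first interaction asks whether the difference between IL-17 single positive and double negative cells depends on the culture. The second asks whether the difference made by IL-10 depends on IL-17.

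Lists of genes were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 29 lists have 457 members: Th17 core, STAT3 and Th17 priming, IL-2 STAT5 targets, Tfh, naive and memory, Treg, IL-10 regulators, co-inhibitory, Th1 and cytotoxic, Th2, pathogenic Th17, non-pathogenic Th17, effector cytokines and chemokines, N-glycan branching, hexosamine pathway, glycolysis, glutamine and amino acid uptake, cholesterol synthesis, cell cycle, survival and apoptosis, immediate early, interferon response, unfolded protein response, heat shock and stress, mitochondrially encoded, and markers of B cells, of myeloid cells, of CD8 T, NK and gamma delta T cells, and of erythroid cells. In the table, 14 members were not found, 13 of them the mitochondrially encoded genes, so that list is not analysed here; 2 others were matched by another symbol. Some genes stand in several lists, such as Maf, Il2ra and Il24. Each list was tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 3, adjusted over the lists of a comparison. Of the 270 list tests, 68 passed, and 24 of these 68 also passed with a correlation estimated from the data. The list's median, its mean and the direction of the test differed in sign in 57 of the 270 tests and in 0 of the 68 that passed. For each list, the called members are given among all genes tested and, where that count differs, with p-values adjusted over the list alone.

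The genes named in the text come from a panel of 12, from the 6 largest rises and 6 largest falls of a comparison, and from at most 4 genes per list. Rises and falls were ranked among called genes with a mean of at least 10 CPM in the higher group. Outside the interactions, every library of a group also had to lie above every library of the other. Left out of the ranking were names beginning with Gm and a digit, names ending in Rik, pseudogenes and clone names that end in a point and a number. Some genes that this rule names are not reported here. A few members named under another part of the rule are repeated where a later comparison needs their value. Il17a and Il10 encode the cytokines by which cells were sorted, so a difference in them between gates chosen on that cytokine is not a finding. Both stand in the effector cytokines and chemokines list. Il17a also stands in the Th17 core list and Il10 in the non-pathogenic Th17 list. List results between such gates therefore include them.

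The labels' protocols state that the populations were sorted from the same cultures in each of 3 experiments, so libraries with the same number were taken as paired. The main design has no term for the experiment. A blocked fit with this term was an alternative, and its value is given beside a result where it changes a call or moves a count by more than 1.5 times. Within a comparison, residuals of libraries with the same number correlated between 0.162 and 0.469 in experiments 2 and 3, and between -0.057 and 0.068 in experiment 1.

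The other alternatives planned were RLE size factors, no filter on low counts, a fit of only the groups compared, DESeq2 1.42.0, limma-voom with quality weights, camera with an estimated correlation, fry, and leaving out each library in turn. Fits with robust estimation of the prior spread, without experiment 2 and without 26 genes that were on in some and off in other replicates of a group were added after the data were seen. A gene counted as such where libraries of 1 group differed by at least 10 times and the higher value was at least 5 CPM. Where a fit leaves a group with fewer libraries, these are assumed to vary like the other groups. The quality weights of limma-voom ran from 2.028 to 6.129 in experiment 1 and from 0.303 to 0.809 in experiments 2 and 3. That fit therefore rested mostly on experiment 1.

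The fit was tested on simulated data of the same size and depth, in which 67 genes changed by 1.5 times. For the comparison of unsorted cells, 61.2% of these were called, 82.1% of those changed by 2 times and 100% of those changed by 4 times, with 6 false calls among 168. Of the genes changed by 1.5 times, 35.8% were called in the interaction of culture and IL-17 and 46.3% in that of IL-10 and IL-17, and of those changed by 2 times 73.1% and 77.6%. In these data few genes were changed, none of them among those with the lowest means, and libraries of an experiment were simulated as independent. The rates may therefore not hold for genes with few counts or for paired libraries. Alignment, splicing and transcript isoforms were not analysed here.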

Results

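Gene expression was measured by RNA sequencing in mouse T cells that had been made into Th17 cells for 3 days with added IL-2 or with an antibody that blocks IL-2. From the IL-2 cultures came unsorted live CD4 T cells and 4 sorted populations. These were cells with neither IL-17 nor IL-10 (double negative), with IL-17 alone (IL-17 single positive), with both (double positive) and with IL-10 alone (IL-10 single positive). From the anti-IL-2 cultures came unsorted, double negative and IL-17 single positive cells. Each of these 8 groups had 3 libraries, numbered by experiment, so n = 3 stands behind every mean below. Unsorted libraries with IL-2 held 31.7 ± 3.85 M counts and those with anti-IL-2 29.2 ± 2.98 M. Single libraries ran from 24.7 to 43.6 M. The first principal component took 57.2% of the variance and the second 8.06%. The positions of the main genes on GRCm38 are as follows. Il17a (ENSMUSG00000025929) lies on chromosome 1 from 20730905 to 20734496, Il10 (ENSMUSG00000016529) on chromosome 1 from 131019845 to 131024974, and Mgat5 (ENSMUSG00000036155) on chromosome 1 from 127205015 to 127488336. Maf (ENSMUSG00000055435) lies on chromosome 8 from 115682942 to 115707794, Lrrc32 (ENSMUSG00000090958) on chromosome 7 from 98489283 to 98502181, and Cdc20 (ENSMUSG00000006398) on chromosome 4 from 118432901 to 118437352.

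The first question, which the title of the series poses, was how IL-2 changed Th17 cells and their IL-10. In unsorted cells Il17a was lower with IL-2, at 143 ± 30.6 CPM against 842 ± 91.7 CPM with anti-IL-2, and Il10 was higher, at 22.8 ± 2.29 against 1.19 ± 0.249 CPM. Maf, a transcription factor known to induce Il10 in T cells, rose from 41.3 ± 0.981 CPM with anti-IL-2 to 318 ± 30.2 CPM with IL-2. The log2 changes were -2.56 ± 0.22 (SE) for Il17a, 4.24 ± 0.28 for Il10 and 2.94 ± 0.08 for Maf, with adjusted p of 1.18e-08, 3.68e-10 and 1.54e-15 by edgeR's quasi-likelihood test. Il17f, the neighbour and relative of Il17a, showed -0.22 ± 0.36 (adjusted p = 0.659), and Ifng 2.14 ± 1.73 (adjusted p = 0.333). Il2 itself fell by 2.24 on the log2 scale (adjusted p = 0.0114), a call lost without the unsorted anti-IL-2 library of experiment 3 (0.0612) or the unsorted IL-2 library of experiment 2 (0.0561). Without that last library the Il17f value was 0.003 (adjusted p = 0.997), and without the unsorted IL-2 library of experiment 1 the Ifng value was -1.83 (adjusted p = 0.632).

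Targets of IL-2 and STAT5 signalling rose as a group with IL-2 in unsorted cells: 14 of 25 were higher and 1 was lower (median log2 change 0.46, camera adjusted p = 0.00133). They included Il2ra, the IL-2 receptor alpha chain (0.94 ± 0.10), Socs2, a brake on cytokine signalling (2.62 ± 0.35), Il12rb2, an IL-12 receptor chain (3.80 ± 0.27), and Bcl2, which blocks cell death (0.74 ± 0.06). Genes of regulatory T cells rose too, with 10 of 18 higher and 2 lower (median 0.76, adjusted p = 0.00128). Lrrc32, which holds latent TGFβ on the cell surface, gave the largest rise among the genes that the naming rule ranks, other than Nanog. Nanog was on in some and off in other replicates. Lrrc32 went from 0.371 ± 0.102 to 28.8 ± 3.89 CPM (6.25 ± 0.32, adjusted p = 7.06e-12). Entpd1, the ectoenzyme CD39, rose by 3.39 ± 0.15, Izumo1r by 3.33 ± 0.19 and Ctla4 by 0.99 ± 0.07. Foxp3 rose by 1.21 ± 0.38 (adjusted p = 0.013), which was lost without the unsorted IL-2 library of experiment 2 (0.106). Genes of naive and memory T cells rose, 11 of 13 with 0 lower (median 0.77, adjusted p = 9.04e-06). Among them were the transcription factor genes Tcf7 (1.53 ± 0.16) and Lef1 (1.12 ± 0.07).

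Genes of the non-pathogenic Th17 list, to which Maf belongs, also rose in unsorted cells with IL-2: 6 of 8 were higher and 2 lower (median 1.21, adjusted p = 0.00749). Of the cell cycle list, 16 of 25 were higher and 0 lower (17 adjusted over the list alone), such as Cdc20 (0.66 ± 0.09) and Aurka (0.58 ± 0.08), both needed in mitosis. Its adjusted p was 0.000284, and adjusted p = 0.496 with an estimated correlation. Lower with IL-2 were immediate early genes, 13 of 20 with 2 higher (3 higher adjusted over the list alone; median -0.88, adjusted p = 0.00451), and adjusted p = 0.202 with an estimated correlation. They included Egr3 (-2.70 ± 0.31), Nr4a1 (-1.72 ± 0.20) and Nr4a3 (-1.53 ± 0.11), which are induced by receptor stimulation. Of the heat shock and stress list 6 of 11 were lower and 0 higher (adjusted p = 0.0384), such as Hsph1 (-0.86 ± 0.09), and adjusted p = 0.216 with an estimated correlation. That call ended in the blocked fit (0.0517) and without the unsorted anti-IL-2 library of experiment 3 (0.0952). The other large rises were Ly6c1 (5.28 ± 0.49), Treml2 (5.01 ± 0.50) and Gja5, a gap junction protein (5.08 ± 0.84). The large falls were Fosb, an AP-1 factor (-4.80 ± 0.52), the kinase gene Dclk1 (-4.71 ± 0.40), Fscn1, which bundles actin (-4.59 ± 0.36), Crtam, an adhesion receptor of activated T cells (-4.42 ± 0.23) and Tshb (-4.36 ± 0.50).

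For glycosylation genes, the N-glycan branching list had 3 of 17 members higher and 3 lower with IL-2 in unsorted cells (adjusted p = 0.971). B4galt1 (0.51 ± 0.06), St3gal4 (0.72 ± 0.09) and Mgat4a (0.59 ± 0.15), all glycosyltransferases, were higher, and Slc35a2, which carries UDP-galactose, was lower (-0.38 ± 0.07). Mgat5, which makes the most branched N-glycans, gave 0.07 ± 0.13 (adjusted p = 0.709). Its value was -0.03 without the unsorted IL-2 library of experiment 2 and -0.01 without the unsorted anti-IL-2 library of experiment 3. The hexosamine pathway, which makes the UDP-GlcNAc that branching uses, had 6 of 11 higher and 2 lower (adjusted p = 0.228). Th17 core genes had 3 of 13 higher and 7 lower (adjusted p = 0.167): Il24 (6.24 ± 0.47) and Ltb4r1 (2.97 ± 0.19) rose, and Tmem176a (-3.79 ± 0.19) and Tmem176b (-3.18 ± 0.19) fell. Of the regulators of Il10, 6 of 15 were higher and 3 lower (adjusted p = 0.163). Prdm1 rose by 1.70 ± 0.51 (adjusted p = 0.0093), lost without the unsorted IL-2 library of experiment 3 (0.0559) or the unsorted anti-IL-2 library of experiment 1 (0.0554). Bcl6 rose by 0.58 ± 0.21 (adjusted p = 0.0285), and 4 of the 6 fits that left out 1 library lost that call, at most without the unsorted IL-2 library of experiment 3 (0.164).

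The remaining lists did not pass in unsorted cells. The counts higher and lower were 7 and 5 of 14 for STAT3 and Th17 priming (8 and 5 adjusted over the list alone, adjusted p = 0.0913), 3 and 7 of 14 for Tfh (0.205). They were 6 and 3 of 13 for co-inhibitory (0.108), 3 and 4 of 14 for Th1 and cytotoxic (0.971) and 2 and 2 of 5 for Th2 (0.958). They were 3 and 3 of 15 for pathogenic Th17 (0.971), 5 and 5 of 23 for effector cytokines and chemokines (0.989). For metabolism they were 4 and 8 of 20 for glycolysis (4 and 9 adjusted over the list alone, 0.606) and 5 and 6 of 18 for glutamine and amino acid uptake (0.981), and 4 and 8 of 21 for cholesterol synthesis (4 and 9 adjusted over the list alone, 0.556). They were 5 and 4 of 15 for survival and apoptosis (5 and 5 adjusted over the list alone, 0.79), 4 and 3 of 13 for interferon response (0.971) and 3 and 2 of 16 for the unfolded protein response (0.971). Markers of B cells had 2 of 7 higher and 4 lower (0.297), among them Cd79b at 0.0587 ± 0.0563 CPM with IL-2 and 1.26 ± 0.467 CPM with anti-IL-2, and Cd74 (-1.27 ± 0.23). Markers of CD8 T, NK and gamma delta T cells had 3 of 5 higher and 0 lower (0.0924), such as Klrd1 (3.04 ± 0.41). Markers of myeloid cells had 0 of 5 called (0.79). The single measured marker of erythroid cells, Alas2, gave -0.46 ± 0.54 (adjusted p = 0.521), and its list was not tested.

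In all, 8453 of 18479 genes differed with IL-2 in unsorted cells, 4100 higher and 4353 lower (3921 and 3916 with no filter on low counts). At least 2-fold, 894 were higher and 1751 lower. The RNA of the cultures differed as well: the 10 highest genes took 4.02% ± 0.060 of counts with IL-2 and 3.35% ± 0.339 with anti-IL-2, and ribosomal protein genes 3.00% ± 0.038 and 2.62% ± 0.138. A set of 1907 olfactory and vomeronasal receptor genes outside those tested together took 2.82 ± 0.11 CPM with IL-2 and 6.34 ± 0.34 with anti-IL-2.

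**Figure D1:**
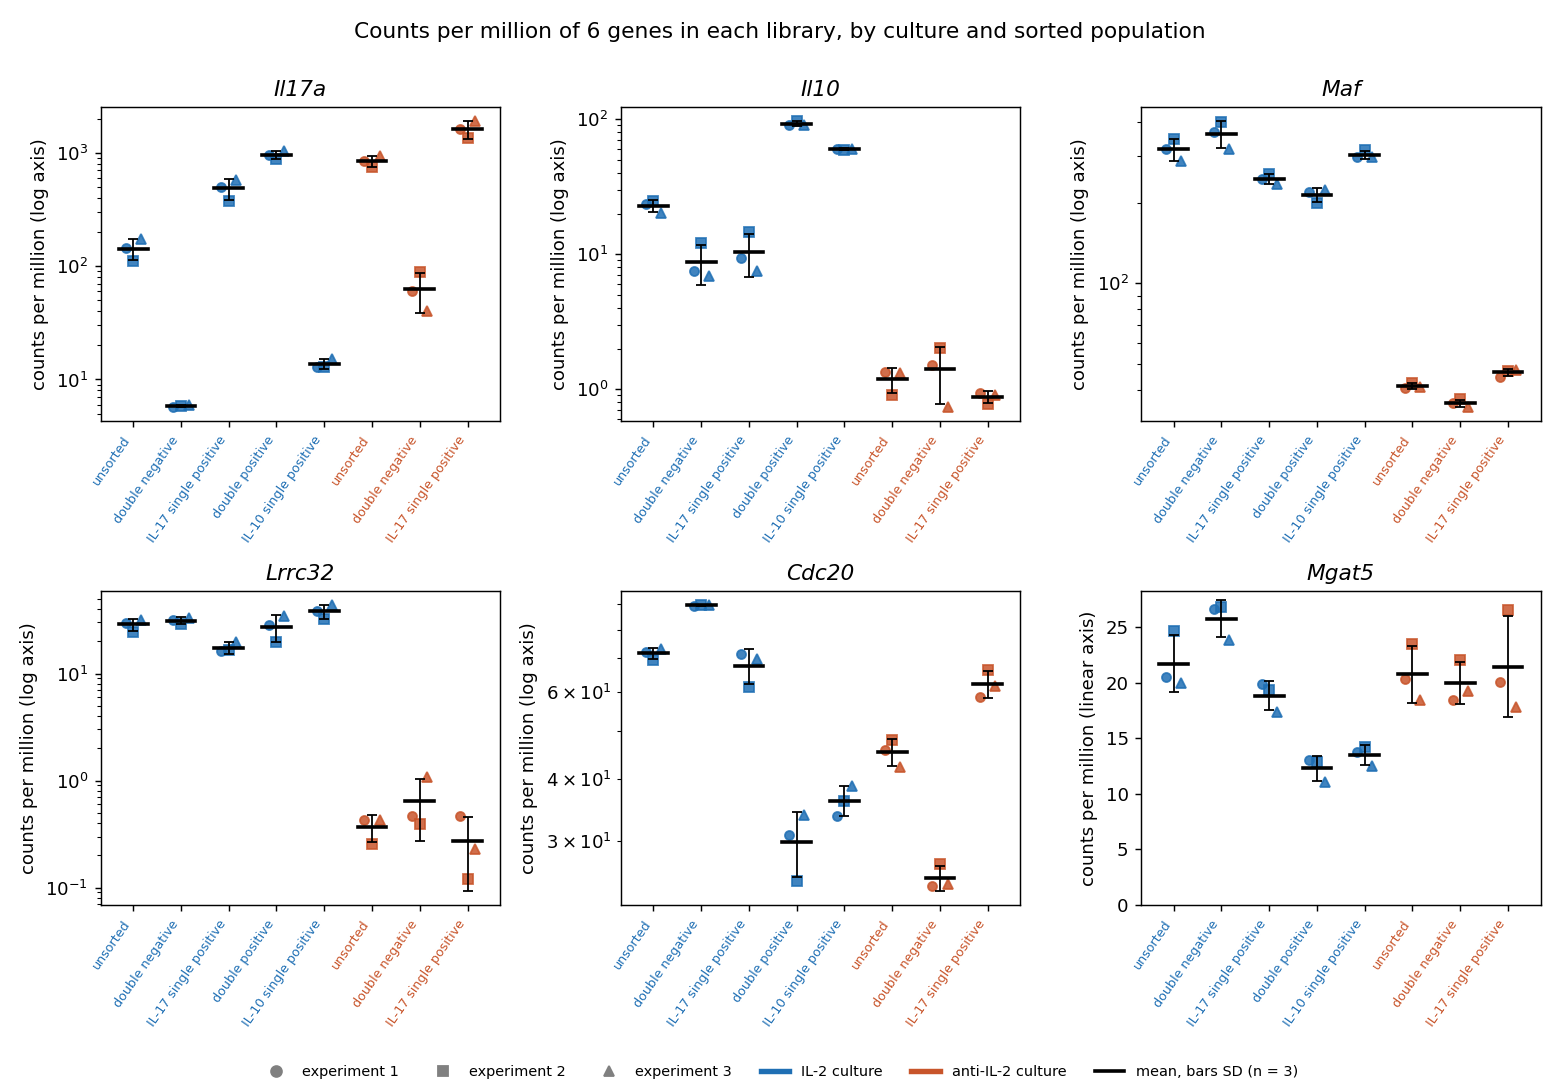
CPM of Il17a, Il10, Maf, Lrrc32, Cdc20 and Mgat5 (y axes, log except Mgat5) in the 24 libraries (points) by group (x axis), with the mean and SD of 3 libraries. Maf averages 318 CPM in unsorted cells with IL-2 and 41.3 CPM with anti-IL-2, and Mgat5 12.3 CPM in double positive and 25.7 CPM in double negative cells with IL-2.

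The same comparison within sorted cells asks whether the effect of IL-2 holds in cells of the same gate. Within a gate, Il17a and Il10 still differed between the cultures. In double negative cells Maf rose by 3.35 ± 0.08 with IL-2, Lrrc32 by 5.64 ± 0.29 and Entpd1 by 3.53 ± 0.15. In IL-17 single positive cells they rose by 2.41 ± 0.08, 6.06 ± 0.34 and 2.96 ± 0.15. Il2ra rose by 0.99 ± 0.10 in double negative and 0.81 ± 0.10 in IL-17 single positive cells, and Il12rb2 by 3.95 ± 0.27 and 4.29 ± 0.29. Il17a was lower with IL-2 even among cells gated as IL-17 single positive, at 485 ± 103 against 1616 ± 283 CPM (-1.74 ± 0.21, adjusted p = 1.67e-06), and among double negative cells, at 5.86 ± 0.11 against 63.1 ± 24.1 CPM. Il10 was higher in both, by 2.60 ± 0.27 and 3.57 ± 0.30. Procr, a receptor of protein C, rose by 5.46 ± 0.62 and 4.75 ± 0.58, and Treml2 by 5.32 ± 0.51 and 4.87 ± 0.50. Fosb (-5.04 ± 0.51 and -4.59 ± 0.52), Fscn1 (-4.52 ± 0.35 and -3.98 ± 0.36) and Crtam (-4.38 ± 0.23 and -3.88 ± 0.22) fell in both. Other large falls were Rag1, a recombinase of antigen receptor genes (-4.81 ± 0.35), and Olfm2 (-4.38 ± 0.56) in double negative cells, and Zfp651 (-3.52 ± 0.22) and Arntl2 (-3.52 ± 0.43) in IL-17 single positive cells.

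Other genes are given below for 1 or both of these populations, and several of their calls were lost without single libraries. A value given for 1 population does not mark a difference between them. Of these genes, only Il6ra was called in the interaction of culture and IL-17 (0.213). Il17f gave -0.36 ± 0.36 in double negative cells (adjusted p = 0.429), called in the blocked fit (adjusted p = 0.0041), and 0.03 ± 0.36 in IL-17 single positive cells (adjusted p = 0.958). Mgat5 was higher with IL-2 in double negative cells by 0.37 ± 0.13 (adjusted p = 0.019), lost in 4 of 6 fits without 1 library, at most without the anti-IL-2 library of experiment 1 (0.0796). Il2 fell by 2.60 in double negative cells and by 1.80 in IL-17 single positive cells, where 4 of 6 fits without 1 library lost the call, at most without the anti-IL-2 library of experiment 3 (0.164). Prdm1 rose by 1.27 ± 0.49 in double negative cells (at most 0.158, without the anti-IL-2 library of experiment 1) and by 1.48 ± 0.58 in IL-17 single positive cells (at most 0.156, without the anti-IL-2 library of experiment 2), and lost its call in 4 and 5 of the 6 fits. Foxp3 rose by 1.42 ± 0.37 in double negative cells, and in IL-17 single positive cells Bcl6 rose by 1.00 ± 0.21, Il6ra, an IL-6 receptor chain, by 0.93 ± 0.05 and Ahr by 1.13 ± 0.12.

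Several gene groups followed IL-2 in both sorted populations. Naive and memory genes were higher in 11 of 13 in double negative cells (adjusted p = 0.000268) and 12 of 13 in IL-17 single positive cells (7.88e-07), with 0 lower. Treg genes were higher in 12 and 10 of 18, with 2 lower in each (0.00296 and 0.00519). IL-2 STAT5 targets were higher in 14 of 25 with 3 lower (0.029) and in 15 of 25 with 0 lower (0.00018); in double negative cells adjusted p = 0.0547 with an estimated correlation. Non-pathogenic Th17 genes were higher in 6 of 8 with 2 lower (0.0181) and in 5 of 8 with 1 lower (0.00534); in double negative cells adjusted p = 0.0547 with an estimated correlation. Immediate early genes were lower in 13 and 12 of 20, with 2 higher in each (3 higher and 13 lower adjusted over the list alone; 0.00296 and 0.00519), with adjusted p = 0.154 and adjusted p = 0.162 with an estimated correlation. Heat shock and stress genes were lower in 7 of 11 in each, with 1 and 0 higher (0.0314 and 0.0133), with adjusted p = 0.213 and adjusted p = 0.162 with an estimated correlation. The first of these calls was lost without the anti-IL-2 double negative library of experiment 3 (0.0597). STAT3 and Th17 priming genes were higher in 7 of 14 in IL-17 single positive cells with 3 lower (8 and 4 adjusted over the list alone; 0.0348), with adjusted p = 0.219 with an estimated correlation and 0.147 in the blocked fit.

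Cell cycle genes separated the populations. In double negative cells 25 of 25 were higher with IL-2 (median 1.39, adjusted p = 1.79e-13), with adjusted p = 0.213 with an estimated correlation, such as Cdc20 (1.83 ± 0.09), Ccnb1 (1.71 ± 0.09), Plk1 (1.77 ± 0.12) and Aurka (1.68 ± 0.08). In IL-17 single positive cells 1 was higher and 3 lower (0 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.88). Between the cultures 9629 genes differed in double negative cells, 4700 higher and 4929 lower with IL-2 (6367 and 6335 with limma-voom). In IL-17 single positive cells 7586 differed, 3735 higher and 3851 lower (3568 and 3465 with no filter on low counts). Across genes, which are not independent replicates, the log2 changes in both populations correlated with Pearson's r = 0.76 (0.416 with no filter on low counts) and Spearman's rho = 0.734, 1 of 3 such pairs compared. Of 6020 genes called in both, 5928 (98.5%) had the same direction. Zbed6 and Fam89b rose in double negative cells, with Zbed6 at 0 in all 3 anti-IL-2 libraries and Fam89b at 0 in 2 of them, so no fold is given. The Zbed6 call was lost without the anti-IL-2 library of experiment 1 (0.0558) or 2 (0.0512) and with limma-voom (0.458). The Fam89b call was lost with limma-voom (0.0511) and with DESeq2, which gave no adjusted p.

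Within the IL-2 cultures, IL-17 single positive cells were compared with double negative cells to find what goes with IL-17 production. Besides Il17a, the sort gene, IL-17 single positive cells had more Il17f (754 ± 289 against 212 ± 88.6 CPM, 1.83 ± 0.37, adjusted p = 0.0062), more Il3, a growth factor (2.62 ± 0.51), and more of the kinase gene Lrrk2 (1.63 ± 0.25). The LIM-domain gene Fhl2 rose from 4.61 ± 0.607 to 13.3 ± 0.477 CPM (1.53 ± 0.09, adjusted p = 1.21e-09). Th17 core genes, Il17a among them, rose in 8 of 13 with 0 lower (12 adjusted over the list alone; median 1.30, adjusted p = 7.1e-17), such as Tmem176b (1.70 ± 0.20), Tmem176a (1.42 ± 0.20) and Il24 (1.48 ± 0.27). Hexosamine pathway genes rose in 4 of 11 with 0 lower (median 0.27, adjusted p = 0.000944), among them Gfpt1, its first enzyme (0.30 ± 0.06), Pgm3 (0.27 ± 0.05) and Ogt, which attaches GlcNAc to proteins (0.30 ± 0.06). Gfpt2 rose by 0.93 ± 0.24, with the call lost in 5 of 6 fits, at most without the double negative library of experiment 1 (0.141).

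Maf was lower in IL-17 single positive cells, at 246 ± 10.7 against 363 ± 41.8 CPM (-0.56 ± 0.07, adjusted p = 0.000109). Naive and memory genes fell in 5 of 13 with 1 higher (median -0.19, adjusted p = 0.00131), and interferon response genes in 1 of 13 with 0 higher (4 adjusted over the list alone; median -0.45, 0.00109), such as Gbp2 (-0.44 ± 0.08). IL-10 regulators, Maf among them, fell in 2 of 15 with 0 higher (1 higher and 3 lower adjusted over the list alone; 0.00629), and non-pathogenic Th17 genes in 3 of 8 with 1 higher (1 and 6 adjusted over the list alone; 0.00424). Slfn1 (-1.38 ± 0.13) and Ephx1 (-1.27 ± 0.13) were other large falls. Serinc4 (-2.25 ± 0.51), Klf2 (-1.61 ± 0.39), Socs3 (-1.49 ± 0.35), S1pr1 (-1.36 ± 0.35), Foxp3 (-1.55 ± 0.37) and Mgat5 (-0.45 ± 0.13, adjusted p = 0.0469) fell too. Each of these 6 calls was lost without single libraries: at most without the IL-17 single positive library of experiment 1 for Serinc4 (0.0769) and of experiment 3 for Socs3 (0.0743) and Mgat5 (0.169), and without the double negative library of experiment 2 for Klf2 (0.102), S1pr1 (0.152) and Foxp3 (0.139). The Mgat5 call was lost whichever library of the compared groups was left out (adjusted p from 0.0631 to 0.169), and with no filter on low counts (0.0611). When only the compared groups were fitted, the calls of Foxp3 (0.0899) and S1pr1 (0.062) were lost. Other annotated genes overlap 100% of the exons of Serinc4, and its unsorted IL-2 libraries held 1.684, 12.65 and 2.077 CPM.

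Effector cytokines and chemokines, Il17a among them, rose in 5 of 23 with 1 lower (7 and 1 adjusted over the list alone). Their camera adjusted p was 4.23e-06, and 0.241 with an estimated correlation. Tnfsf11, which encodes RANKL, rose by 1.28 ± 0.15. Pathogenic Th17 genes rose in 3 of 15 (8 and 1 lower adjusted over the list alone). Their camera adjusted p was 0.00233, and 0.305 with an estimated correlation. Cxcl3, of this list, rose by 1.83 ± 0.35. Cell cycle genes fell in 5 of 25 with 0 higher (10 adjusted over the list alone; median -0.29, 2.84e-09), with adjusted p = 0.25 with an estimated correlation. Among them Cdc20 fell by 0.41, lost without the IL-17 single positive library of experiment 2 (0.0573). STAT3 and Th17 priming genes had 1 of 14 higher and 4 lower (2 and 6 adjusted over the list alone; 0.00337), with adjusted p = 0.0857 with an estimated correlation; Bcl3 fell by 0.70. Glutamine and amino acid uptake genes rose in 3 of 18 (5 adjusted over the list alone; 0.00337), and unfolded protein response genes in 2 of 16 (0.00121), with adjusted p = 0.241 and adjusted p = 0.409 with an estimated correlation. With fry the pathogenic Th17 (0.0611) and unfolded protein response (0.119) calls were lost. Tfh genes rose in 2 of 14 (3 adjusted over the list alone; 0.0468), with adjusted p = 0.241 with an estimated correlation. Without the double negative libraries of experiments 1 or 3 or the IL-17 single positive library of experiment 1 the Tfh call was lost (0.0595, 0.112 and 0.0859). IL-17 single positive and double negative cells differed in 818 genes, 500 higher and 318 lower, and in 2158 in the blocked fit. The balance depended on the fit, with 1817 higher and 1787 lower with limma-voom and 498 and 441 when only the compared groups were fitted. The count was 402, 502 and 507 without the double negative library of experiment 1, 2 or 3, and 392 and 473 without the IL-17 single positive library of experiment 1 or 2.

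In the anti-IL-2 cultures the same comparison gave partly other genes. Il17f rose from 272 ± 110 to 738 ± 184 CPM (1.44 ± 0.37, adjusted p = 0.00865), Il3 by 2.65 ± 0.52 and Lrrk2 by 2.46 ± 0.24. Igfbp7, a binder of insulin-like growth factors, rose by 2.93 ± 0.44, Spp1, the cytokine osteopontin, by 2.08 ± 0.21, Inhba, an activin subunit, by 2.03 ± 0.11 and the chemokine receptor Ccr6 by 1.94 ± 0.26. Socs3, which inhibits STAT3 signalling (-2.02 ± 0.35), Klf2, a factor of quiescent T cells (-1.83 ± 0.39), the phosphodiesterase gene Pde2a (-1.64 ± 0.17), Pou6f1 (-1.57 ± 0.32) and Fscn1 (-1.52 ± 0.29) fell. The call of Klf2 was lost when only the compared groups were fitted (adjusted p = 0.0638). Maf was higher in the IL-17 single positive cells here, at 46.5 ± 1.5 against 35.7 ± 1.12 CPM (0.38 ± 0.08, adjusted p = 0.0012).

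Cell cycle genes rose in 23 of 25 with 0 lower in these anti-IL-2 cells (25 adjusted over the list alone; median 1.15, adjusted p = 2.95e-26), such as Cdk1 (1.38 ± 0.12), Aurka (1.34 ± 0.08), Cdc20 (1.30 ± 0.09) and Ccnb1 (1.28 ± 0.09), with adjusted p = 0.0944 with an estimated correlation. Th17 core genes rose in 7 of 13 with 0 lower (median 1.39, 3.57e-06), and naive and memory genes fell in 6 of 13 with 1 higher (median -0.54, 0.000336), such as Lef1 (-0.75 ± 0.07) and Foxp1 (-0.47 ± 0.05), while Il7r rose by 1.54 ± 0.15. Glutamine and amino acid uptake genes rose in 8 of 18 with 0 lower (10 and 1 adjusted over the list alone; 3.54e-05), with adjusted p = 0.132 with an estimated correlation, such as Asns (0.72 ± 0.09), Psat1 (0.61 ± 0.06) and Shmt2 (0.33 ± 0.05), enzymes of amino acid synthesis. Unfolded protein response genes rose in 6 of 16 (10 adjusted over the list alone; 9.92e-05), such as Trib3 (0.51 ± 0.04), with adjusted p = 0.418 with an estimated correlation. Effector cytokines and chemokines, Il17a among them, rose in 8 of 23 (10 adjusted over the list alone, 0.00156). Pathogenic Th17 genes rose in 6 of 15 (9 adjusted over the list alone, 0.00612). With an estimated correlation these lists had adjusted p of 0.45 and 0.437. Immediate early genes fell in 6 of 20 (8 adjusted over the list alone; 0.0174), such as Nfkbia (-0.59 ± 0.06). So did STAT3 and Th17 priming genes in 5 of 14 with 1 higher (7 and 1 adjusted over the list alone; 0.0322), with adjusted p = 0.227 and adjusted p = 0.227 with an estimated correlation. Without the double negative library of experiment 2 the pathogenic Th17 (0.0632) and STAT3 (0.078) calls were lost, the first also without the IL-17 single positive library of experiment 3 (0.0557). In all, 3205 genes differed, 1731 higher and 1474 lower, against 5102 in the blocked fit (2579 and 2523) and 1430 when only the compared groups were fitted (930 and 500). With limma-voom 3905 were higher and 4084 lower, so the balance depended on the fit.

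Whether the IL-17 difference depended on the culture was tested by the interaction, which called 1499 genes, 621 with a more positive difference with IL-2 and 878 with a more negative one. Negative interactions were called for Depdc1b (-2.10 ± 0.21), Pif1 (-2.03 ± 0.25), Ska1 (-1.98 ± 0.25), Mxd3 (-1.96 ± 0.25) and Depdc1a (-1.91 ± 0.15). The cell cycle list had 23 of 25 members with a negative interaction (25 adjusted over the list alone; median -1.41, camera adjusted p = 6.39e-35), with adjusted p = 0.11 with an estimated correlation. The median difference between IL-17 single positive and double negative cells over this list was -0.27, -0.30 and -0.27 in experiments 1 to 3 with IL-2 and between 1.04 and 1.21 with anti-IL-2. Maf fell in IL-17 single positive cells with IL-2 and rose in those with anti-IL-2, and this difference was called (-0.94 ± 0.11, adjusted p = 6.04e-06). Mex3a (1.55 ± 0.25) and Lama5, a laminin chain (1.19 ± 0.23), had positive interactions. Nat8l (1.67 ± 0.46) and Sik1 (1.23 ± 0.34) had too, lost at most without the IL-2 IL-17 single positive library of experiment 2 (0.0911) and the anti-IL-2 double negative library of experiment 2 (0.0759). Across genes the IL-17 differences in the cultures correlated little (r = 0.007, rho = 0.085; r = 0.061 without the 26 genes on in some and off in other replicates), and 363 of 440 genes called in both (82.5%) had the same direction. The count of interactions was 3235 in the blocked fit, 1647 of them positive and 1588 negative, and 966 when only the compared groups were fitted. With limma-voom 2798 were positive and 2709 negative, so the larger number of negative ones depended on the fit.

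**Figure D2:**
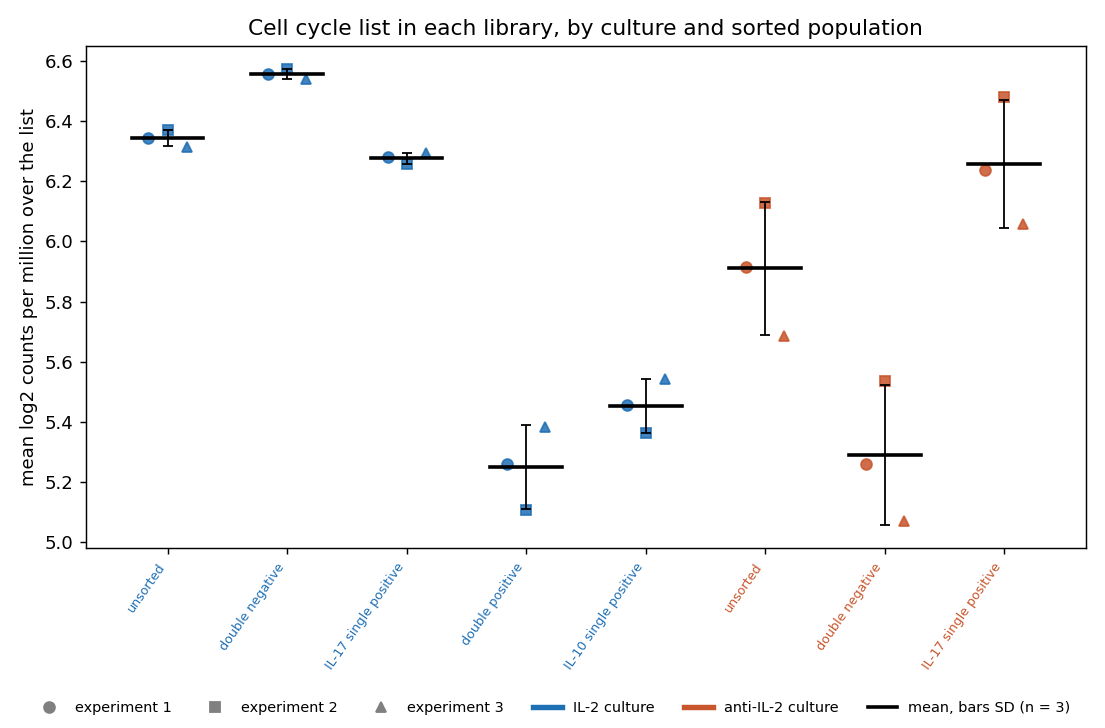
Mean log2 CPM over the 25 cell cycle genes (y axis) in each of the 24 libraries (points) by group (x axis), with the mean and SD of 3 libraries. With IL-2 the double negative cells average 6.56 and the double positive cells 5.25, and with anti-IL-2 the double negative cells average 5.29 and the IL-17 single positive cells 6.26.

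Cells that made IL-10 besides IL-17 were then compared with those that made IL-17 alone, all with IL-2. Double positive cells had less cell cycle expression: 25 of 25 genes of the list fell (median -1.13, adjusted p = 3.26e-38), such as Ccnb2 (-1.46 ± 0.14), Ccnb1 (-1.27 ± 0.09), Plk1 (-1.31 ± 0.12) and Cdc20, at 29.9 ± 4.51 against 67.5 ± 5.50 CPM. Iqgap3 (-1.74 ± 0.31), Pif1 (-1.64 ± 0.18), Parpbp (-1.49 ± 0.14) and Neil3 (-1.49 ± 0.25) fell too. Besides Il10 itself, Il24 rose from 3.73 ± 0.682 to 15.6 ± 1.79 CPM (2.06 ± 0.24, adjusted p = 1.82e-05). Areg, the growth factor amphiregulin, rose from 5.99 ± 0.32 to 19.4 ± 3.65 CPM (1.70 ± 0.22), and the NK receptor genes Klrc1 (1.28 ± 0.28) and Klrc2 (1.25 ± 0.27). Il17a was higher too (0.98 ± 0.21, adjusted p = 0.0038), at 958 ± 84.4 against 485 ± 103 CPM. Gad1 rose by 1.21 ± 0.29, lost without the double positive library of experiment 2 (0.0844) or the IL-17 single positive library of experiment 3 (0.0635).

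Hexosamine pathway genes rose in 5 of 11 in double positive cells with 0 lower (5 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.000769): Pgm3 (0.38 ± 0.05), Gfpt1 (0.37 ± 0.05), Ogt (0.31 ± 0.06) and Uap1 (0.23 ± 0.05) were among them. Mgat5 fell from 18.8 ± 1.34 to 12.3 ± 1.12 CPM (-0.61 ± 0.13, adjusted p = 0.0038). N-glycan branching genes as a list had 4 of 17 higher and 2 lower (4 and 4 adjusted over the list alone; adjusted p = 0.842). Unfolded protein response genes rose in 7 of 16 with 0 lower (12 adjusted over the list alone; median 0.39, 3.26e-07), such as the chaperone gene Dnajb9 (0.77 ± 0.12) and Edem1 (0.33 ± 0.06), with adjusted p = 0.365 with an estimated correlation. Glutamine and amino acid uptake genes rose in 3 of 18 with 1 lower (6 and 1 adjusted over the list alone; 0.00574), such as Got1 (0.42 ± 0.06), with adjusted p = 0.365 with an estimated correlation. Glycolysis (2 of 20, 3 and 1 lower adjusted over the list alone; 0.0295), effector cytokines and chemokines (2 of 23; 0.00368) and pathogenic Th17 genes (1 of 15; 0.0197) rose, with adjusted p = 0.585, adjusted p = 0.418 and adjusted p = 0.418 with an estimated correlation. Each of these last calls was lost without the IL-17 single positive library of experiment 2 (0.471, 0.117 and 0.211) or the double positive library of experiment 3 (0.386, 0.0598 and 0.0696), and with fry (0.223, 0.0869 and 0.113). The effector list holds Il10, a sort gene here, and Il17a, which were both higher. Hk2, which starts glycolysis, rose by 0.51 ± 0.09. Maf showed -0.20 ± 0.07 (adjusted p = 0.0876), called in the blocked fit (adjusted p = 0.0284). These populations differed in 1765 genes, 713 higher and 1052 lower (1099 and 1163 with DESeq2), and in 3439 in the blocked fit. The count was 1172 without the IL-17 single positive library of experiment 1 and 1081 without the double positive library of experiment 2.

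IL-10 single positive cells were compared with double negative cells to follow IL-10 without IL-17. Il24 rose by 2.56 ± 0.27, Areg from 2.02 ± 0.198 to 11.2 ± 0.653 CPM (2.48 ± 0.25, adjusted p = 7.3e-07), Il3 by 2.09 ± 0.51, Gad1, an enzyme that makes GABA, by 1.94 ± 0.31 and Il17f by 1.77 ± 0.37. Il17a was higher by 1.22 ± 0.26 in these IL-17 negative cells, at 13.7 ± 1.36 against 5.86 ± 0.11 CPM. Foxp3 fell from 12.3 ± 6.74 to 3.70 ± 1.08 CPM (-1.74 ± 0.38, adjusted p = 0.00286), Klf2 by 1.88, Socs3 by 1.73, Serinc4, its exons overlapped in the same way, by 2.33 and Arhgap19, a regulator of division, by 1.78 on the log2 scale. Mgat5 fell from 25.7 ± 1.69 to 13.5 ± 0.898 CPM (-0.93 ± 0.13, adjusted p = 3.37e-05). Maf fell by 0.26 (adjusted p = 0.0155), lost in 4 of 6 fits without 1 library, at most without the double negative library of experiment 2 (0.12). Ccl3 rose by 1.81 ± 0.52, lost at most without the same library (0.101).

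Cell cycle genes fell in 25 of 25 in IL-10 single positive cells (median -1.26, adjusted p = 9.57e-32), such as Birc5 (-1.36 ± 0.11) and Ccnb1 (-1.34 ± 0.09), with adjusted p = 0.0513 with an estimated correlation. Hexosamine pathway genes rose in 6 of 11 with 0 lower (7 adjusted over the list alone; median 0.33, 6.98e-05), such as Ogt (0.47 ± 0.06), Pgm3 (0.42 ± 0.05), Gfpt1 (0.42 ± 0.06) and Uap1 (0.29 ± 0.05). Th17 core genes rose in 5 of 13 with 0 lower (median 0.46, 0.000256), Il24 and Ltb4r1 (0.70 ± 0.16) among them. Unfolded protein response genes rose in 9 of 16 with 0 lower (12 adjusted over the list alone; 1.61e-06), such as Edem1 (0.39 ± 0.06) and Xbp1 (0.32 ± 0.07), with adjusted p = 0.269 with an estimated correlation. Cholesterol synthesis genes fell in 8 of 21 with 0 higher (1 and 10 adjusted over the list alone; 0.00561), such as Dhcr7 (-0.90 ± 0.17) and Cyp51 (-0.48 ± 0.11), with adjusted p = 0.332 with an estimated correlation. Effector cytokines and chemokines, a list that holds the sort gene Il10, rose in 8 of 23 (10 and 1 lower adjusted over the list alone, 0.000173). So did pathogenic Th17 genes in 5 of 15 (0.00323) and glutamine and amino acid uptake genes in 8 of 18 with 1 lower (9 and 1 adjusted over the list alone; 0.000173). These 3 lists gave adjusted p = 0.332, adjusted p = 0.332 and adjusted p = 0.248 with an estimated correlation. N-glycan branching genes had 6 of 17 higher and 7 lower (6 and 10 adjusted over the list alone; 0.563). In all, 2985 genes differed, 1320 higher and 1665 lower (1661 and 1734 with DESeq2), and 4776 in the blocked fit.

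Double positive cells were compared with IL-10 single positive cells to follow IL-17 among IL-10 producers. Besides Il17a, Fhl2 rose from 7.65 ± 0.436 to 17.6 ± 1.23 CPM (adjusted p = 4.55e-08), Vax2, a homeobox gene, by 0.91 ± 0.09 and Inhba by 0.83 ± 0.10. Neurl3, a ubiquitin ligase, fell by 0.67 and Maf by 0.50 on the log2 scale, at 214 ± 12.9 against 302 ± 10.5 CPM (adjusted p = 0.00122). Th17 core genes, Il17a among them, rose in 3 of 13 with 0 lower (7 adjusted over the list alone; median 0.76, 8.12e-14), and naive and memory genes fell in 2 of 13 with 0 higher (1 and 3 adjusted over the list alone; median -0.21, 0.000601). Tmem176b rose by 1.06 ± 0.19, Spp1 by 0.88 ± 0.19 and Gfpt1 by 0.25 ± 0.05, calls lost at most without the IL-10 single positive library of experiment 2 (0.0984) and the double positive library of experiment 2 (0.24 and 0.237). Effector cytokines and chemokines, Il17a among them, rose in 2 of 23 with 0 lower (4 adjusted over the list alone, 5.58e-05). Their adjusted p was 0.394 with an estimated correlation. Cell cycle genes had 0 of 25 called (median -0.20, 3.27e-07) and unfolded protein response genes 0 of 16 (2 higher adjusted over the list alone; median 0.19, 0.00196), with adjusted p = 0.4 and adjusted p = 0.4 with an estimated correlation. The latter was lost without the IL-10 single positive library of experiment 2 (0.0563) or the double positive library of experiment 3 (0.0512), and with fry both were lost (0.21 for cell cycle and 0.239 for unfolded protein response genes).

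Hexosamine pathway genes rose in 2 of 11 of this last comparison (0.042), with adjusted p = 0.173 with an estimated correlation and 0.0634 in the blocked fit. Pathogenic Th17 genes had 0 of 15 called (2 higher adjusted over the list alone; median 0.30, 0.0199), with adjusted p = 0.4 with an estimated correlation and 0.239 with fry. The hexosamine call was lost without the IL-10 single positive library of experiment 3 (0.145) or the double positive library of experiment 1, 2 or 3 (0.0522, 0.0735 and 0.091). The pathogenic Th17 call was lost without the IL-10 single positive library of experiment 1 or 2 (0.052 and 0.097) or the double positive library of experiment 1 or 3 (0.0522 and 0.105). In all, 132 genes differed, 95 higher and 37 lower. The count was 840 in the blocked fit, 317 with DESeq2, 69 with no filter and 29 when only the compared groups were fitted. Without the IL-10 single positive library of experiment 1, 2 or 3 it was 33, 46 and 60, and without the double positive library of experiment 1 or 2 it was 51 and 40.

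The interaction of IL-10 and IL-17, which asks whether IL-10 goes with the same differences in IL-17 producers and non-producers, called 0 genes with edgeR's quasi-likelihood test; 622 had an unadjusted p under 0.05. DESeq2 called 4 genes, limma-voom 13, the blocked fit 6, the fit of only these groups 6 and the fit with no filter 1. Gm45216 was called in each of these fits, and Il17f in the blocked fit (-0.831, adjusted p = 0.0278). Leaving out the IL-17 single positive library of experiment 1 gave 1, and the 11 other such fits gave 0. Mgat5 gave 0.32 ± 0.18 and Maf 0.06 ± 0.10 (adjusted p = 1 for both), and without the double negative library of experiment 2 the Maf value was -0.02. Th17 core genes had a negative median interaction (-0.44, adjusted p = 0.00352) with 0 of 13 called, and interferon response genes a positive one (0.26, 0.0269) with 0 of 13 called, with adjusted p = 0.135 and adjusted p = 0.164 with an estimated correlation and 0.349 and 0.38 with fry. The interferon call was lost in 6 of 12 fits without 1 library, at most without the double positive library of experiment 3 (0.15). Across genes, the IL-10 difference in IL-17 producers and non-producers correlated with r = 0.39 (0.057 with no filter on low counts) and rho = 0.568, and of 1479 genes called in both, 1477 (99.9%) had the same direction.

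**Figure D3:**
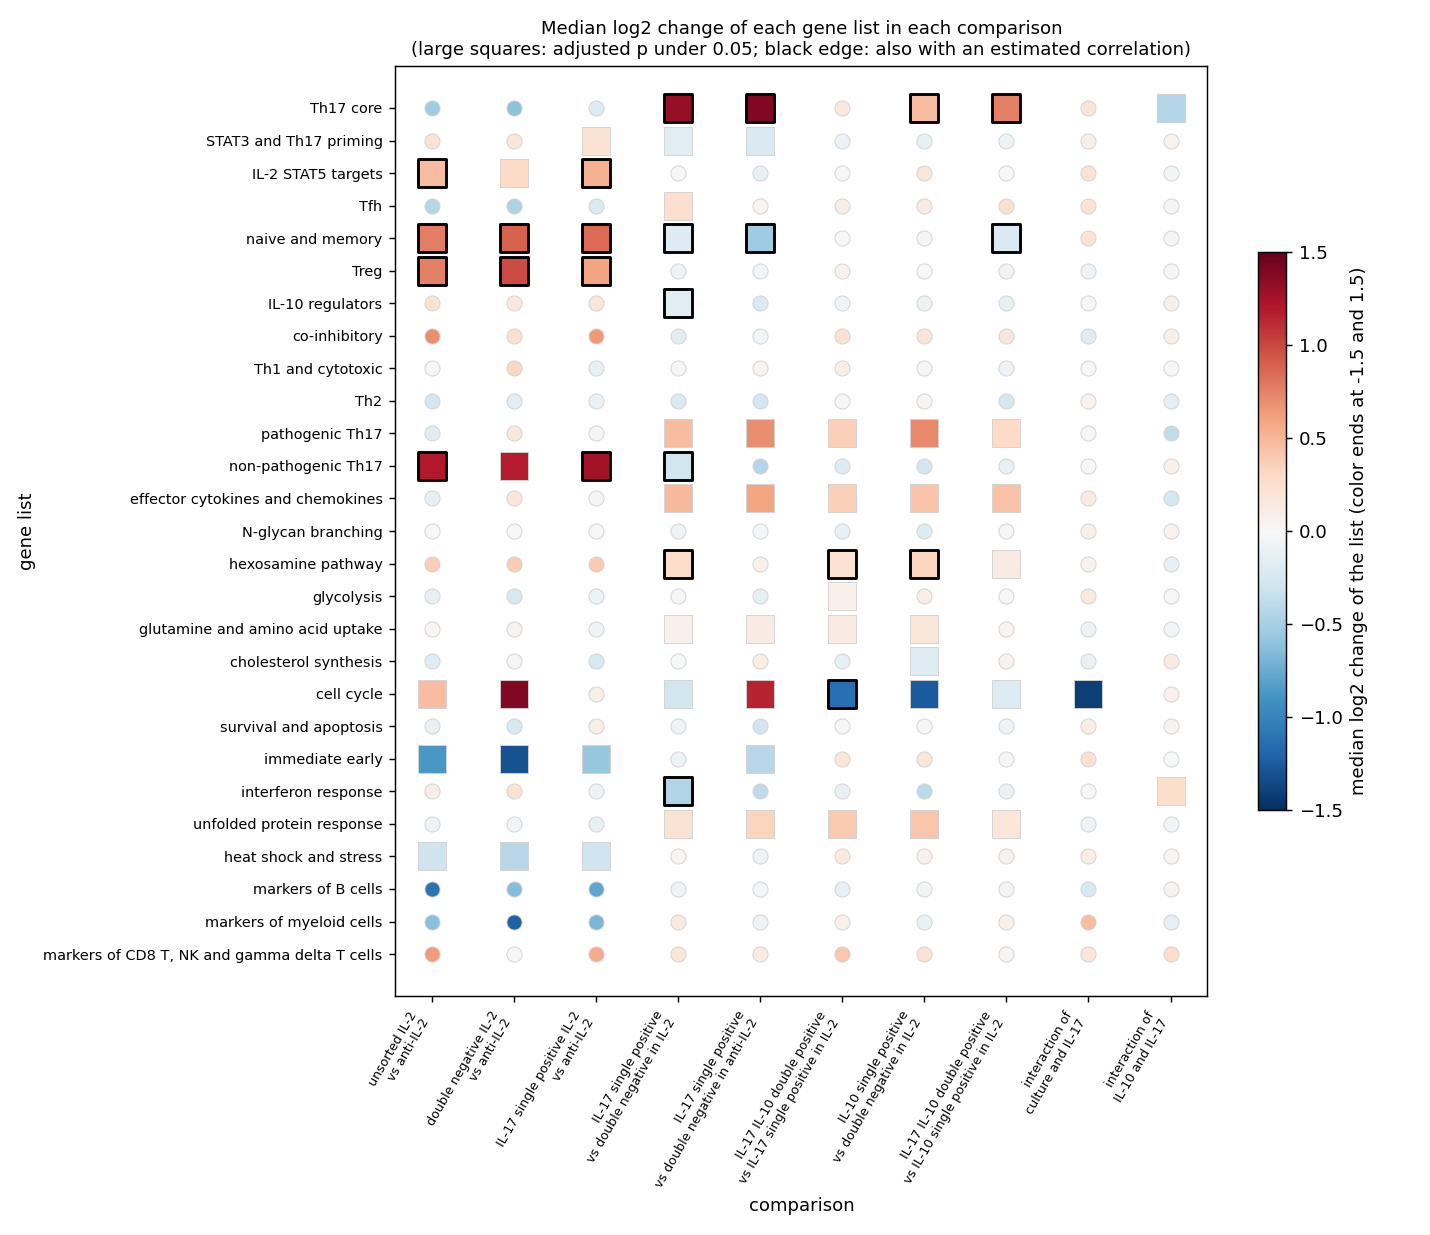
Median log2 change (color) of 27 gene lists (y axis) in 10 comparisons (x axis), with large squares where camera's adjusted p is under 0.05 and a black edge where it also is with an estimated correlation. The cell cycle list has a median of 1.39 for IL-2 in double negative cells and -1.26 for IL-10 single positive against double negative cells.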

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

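The tests of gates and of naive cells below, the count of libraries of 1 culture in the splits, and the fit with reads over receptor genes taken off, were chosen only after the pattern they address was seen. The interaction of culture and IL-17 called 1499 genes. The cell cycle list had a median interaction of -1.408. Of 77 named genes tested for this interaction, 23 were called, against 8.11% of all 18479 genes. The 77 were named in comparisons of the same libraries, so their share is no result about them as a set. Values were positive for Il17a (1.692, a sort gene), Pde2a (1.152), Ogt (0.486), Lef1 (0.409), Foxp1 (0.28) and Il6ra (0.213). They were negative for Cdc20 (-1.705), Plk1 (-1.675), Cdk1 (-1.642), Aurka (-1.634), Ccnb1 (-1.628), Ccnb2 (-1.318), Spp1 (-1.173), Inhba (-0.998), Maf (-0.938) and Il7r (-0.897). They were also negative for Pcna (-0.7), Asns (-0.618), Trib3 (-0.541), Psat1 (-0.537), Shmt2 (-0.333) and Gpt2 (-0.207). Zbed6 had a fitted value of -28.725, which depends on the prior count and is no bound, and its call was lost without the anti-IL-2 double negative library of experiment 1 (0.0548) and without the IL-2 IL-17 single positive library of experiment 1 (0.0528) or 3 (0.051). It was also lost with a robust prior spread (0.0602) and with limma-voom (0.492). In the interaction of IL-10 and IL-17 the medians of the Th17 core list (-0.435) and of the interferon response list (0.263) passed the list test. They had adjusted p of 0.135 and 0.164 with an estimated correlation and of 0.349 and 0.38 with fry.

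The cell cycle list was lower in IL-17 single positive than in double negative cells with IL-2, where 5 of 25 members were called, and higher with anti-IL-2. With an estimated correlation the list passed in neither culture (adjusted p of 0.25 and 0.0944) nor in the interaction (0.11). The tables argue against 1 experiment as the cause, since the highest of the 3 median interactions was -1.338. Gates that favour large, cycling cells among any stained cells were examined in the IL-2 cultures only. There the list had a median of -1.256 in IL-10 single positive cells against double negative cells. This cannot decide on such gates, since with IL-2 the list was lower in both kinds of single positive cells and held no rise to explain. A low level in the IL-10 producers themselves could also hide an effect of the gates. No IL-10 gate was sorted from the anti-IL-2 cultures, where the list was higher in IL-17 single positive cells. Such gates cannot be told apart there. Between the cultures, the list's median change with IL-2 was 1.385 in double negative and 0.083 in IL-17 single positive cells, so the difference lay in the double negative cells more than in the producers. Whether it came from resting cells of naive type in the double negative gate of the anti-IL-2 cultures or from a change within the double negative cells cannot be told apart, because the naive and memory list was not called in the interaction (adjusted p = 0.16). The effect of IL-2 itself on the cells, which the design names, stays open and was not tested.

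In unsorted cells, 1751 genes were at least 2-fold lower and 894 at least 2-fold higher with IL-2. Reads over silent genes in the anti-IL-2 libraries were tested as the cause, after an excess over receptor genes had been seen. Among genes under 1 CPM (847 lower, 307 higher), the median lower gene exceeded the excess per kb of silent olfactory and vomeronasal genes 364.9 times, and among the others (904 lower, 587 higher) 2083.2 times. These ratios decide nothing, since a gene of median length that passes the filter on low counts in the anti-IL-2 libraries and is 2-fold lower has ratios of at least 105 and 71.1, so stray reads over silent genes cannot be told apart by them. Taking each library's reads per kb over all 1949 receptor genes off every gene left 1682 lower and 915 higher genes, a ratio of 1.84. This took off 0.09% of the counts of the unsorted libraries. Genes that pass the filter lie above that rate, so few calls could change. The result shows only that reads spread over all exons at the rate seen over receptor genes are too few to make the difference. Stray reads placed in other ways stay open. Depth is argued against, as thinning to 24.729 M counts per library left a ratio of 1.89 against 1.96. The effect of IL-2 on the cells stays open with the difference in RNA between the cultures.

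Other splits of the same libraries were fitted in the same way. For each of the 8 comparisons of 2 groups, 1 of 10 splits, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 8453 and 0, 9629 and 0, and 7586 and 1 for the culture in unsorted, double negative and IL-17 single positive cells. They were 818 and 1, and 3205 and 731, for IL-17 single positive against double negative cells with IL-2 and with anti-IL-2. They were 1765 and 2 for double positive against IL-17 single positive, 2985 and 0 for IL-10 single positive against double negative, and 132 and 2 for double positive against IL-10 single positive cells. Of the 3 other splits that part all pairs of a numbered experiment, the highest gave 0 in each comparison. For the interaction of culture and IL-17, 5 of 50 splits called at least the real 1499, with 6256 as the highest other, so chance is not excluded by this count. Splits that call several times the real count point to a structure of the samples. The 4 that called more than the real one were those with 5 of the 6 libraries on a side of the contrast from 1 culture (3309 to 6256 genes), and the other splits called at most 70. The 2 other splits that part all pairs gave at most 22. For the interaction of IL-10 and IL-17, with a real count of 0, 50 of 50 splits called at least as many, with 1188 as the highest other. No split can call fewer than 0 genes, so this outcome was fixed in advance and decides nothing.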

How the results depend on the processing

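The fits with a robust prior spread, without experiment 2 and without the 26 genes on in some and off in other replicates were chosen after seeing the data. Of the gene results, for which the last 2 of these were not run, 3426 kept direction and side of the threshold, 215 lost the call, 3 gained it and 10 reversed. Of the list results, 611 kept and 87 lost the call, 44 of them with an estimated correlation and 10 with fry. Of the counts and correlations, 157 stayed within 1.5 times or the spread and 41 moved. RLE size factors moved 0 of 14 of them, robust prior spread 0 of 10 and the fit without experiment 2 0 of the 6 it was run for. In the order of IL-17 against double negative with IL-2 and with anti-IL-2, double positive against IL-17, IL-10 against double negative, double positive against IL-10, and the culture and IL-10 interactions, the counts 818, 3205, 1765, 2985, 132, 1499 and 0 became 2158, 5102, 3439, 4776, 840, 3235 and 6 in the blocked fit. With limma-voom, which gave experiment 1 the highest weights, they became 3604, 7989, 4162, 5651, 719, 5507 and 13. Fitting only the groups compared turned 3205, 132, 1499 and 0 into 1430, 29, 966 and 6. DESeq2 turned 132 and 0 into 317 and 4, and no filter into 69 and 1. Leaving out 1 library, 818 became 392 to 569, 1765 became 1081 to 1474, 132 became 33 to 106 and 0 became 0 to 1. These fits have fewer samples. The concordance of fold changes: culture effect in double negative and IL-17 single positive cells, was 0.416 with no filter, which adds genes with few counts, and 0.785 without the 26 genes, against 0.76. The concordance of fold changes: IL-17 effect in IL-2 and anti-IL-2, was 0.061 without the 26 genes, against 0.007. The concordance of fold changes: IL-10 effect in IL-17 producers and non-producers, was 0.057 with no filter, against 0.39. The list tests passing were 24 with an estimated correlation and 125 with fry, 58 of the 68 among them, against 68. Uncalled values that reversed were those of Il17f in IL-17 single positive cells by culture (-0.016 blocked, -0.012 with limma-voom, -0.251 to 0.298 leaving out 1 library). Leaving out 1 library also reversed, in unsorted cells, Il17f (-0.449 to 0.003), Ifng (-1.829 to 2.676) and Mgat5 (-0.034 to 0.158), and Maf in the IL-10 interaction (-0.021 to 0.145). Where no reason is given, the cause was not tested. Of 53342 genes, 18479 passed the filter on low counts, and how far depth set this number was not tested.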

Other observations

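The genes below were picked from these same counts, and the fit without them was chosen after seeing the data. The tests address this pattern and were not in the plan fixed before the data were examined. In 26 genes some libraries of a group were high and others near 0, as in Zbed6, at 0, 119 and 0 CPM in the 3 unsorted IL-2 libraries and at 110.3, 107 and 113.6 CPM in the double negative IL-2 libraries. Nanog was at 15.52, 0.1066 and 14.83 CPM in the unsorted IL-2 libraries. With reads assigned between overlapping annotated genes, such genes may switch with small differences between libraries. Of the 26 genes 73.1% overlapped the exons of another gene, against a median of 34.6% in 10000 random sets matched on expression, a percentile of 100, as this explanation needs. It does not cover each gene, since 7 of the 26, Nanog and H2-Q1 among them, have 0% of their exons overlapped. A difference between experiments cannot be told apart. That 0 of these genes had off libraries made up only of whole experiments was set to count against it, but this bound was wrong, since 1 off library in another experiment fails it. In 15 of the 26 genes all libraries of an experiment in a culture were off while others in that culture were not. No biological explanation was tested.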
